A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

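The 6 samples were yeast cultures of strain DBY746 grown at 30 °C from 0.002 to 2 A600 units per ml, 3 without and 3 with 300 ng/ml myriocin, both with 0.3% ethanol, per the labels' protocols. Biotin-labelled cRNA from total RNA was hybridised to a single-colour 3' expression array. The deposited values are log2 signals, 1 per probe set, already normalised by the authors. The tool named for the samples is Partek, and its version and the summarisation and normalisation method are not given in the sources used here. That the deposited values are log2 was settled from the files: differences of group means equal the log2 of the ratio column in the authors' fold change table to within 8.48e-05. The same table holds the authors' p-values per probe set, which an equal-variance comparison of these values returned to within 0.00564 on the log10 scale, and a signed fold score with its F statistic, per the file headers. One row of the authors' fold change table carries the name CTT1 in place of a probe set and a signed fold of -4243.52, the value that their longer list gives for YOR387C as -4243.5; CTT1's own probe set is listed there at 88.276. That row was read as YOR387C only for checking, and each value in the report comes from the value table.

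Genes were named from the array's platform annotation, updated through the RefSeq table of assembly R64, or else from the authors' table (127 probe sets). Of 5900 probe sets, 184 were controls, 5545 named 1 gene, 82 named several and 89 were unnamed here. Only probe sets naming 1 gene were tested, and the brightest was used for the 25 genes with more than 1, of which 3 had probe sets that differed by over 1 log2 unit in log2 fold change and 0 had calls in opposite directions. Probe sets can still read close paralogs, so values of ribosomal protein, seripauperin and hexose transporter genes are uncertain in part. No array build is named in the sources used here, so no coordinates are given.

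Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), with no covariate and no filter on signal. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 37 lists with at least 5 measured members. The mitochondrial DNA-encoded list had 0 measured members. One member of the cell wall list, MLP1, is the gene of a nuclear pore protein and was meant as an alias of KDX1, and the list was kept as fixed. The tests, the lists and the rule for named genes were set before the data were examined. The rule names the sphingolipid synthesis genes that passed with LCB1, LCB2, TSC3, ORM1 and ORM2 in any case, the 12 highest and 12 lowest called genes whose groups do not overlap, up to 4 called members in the direction of each shifted list and 2 against it, and up to 2 called members of other lists. It takes 157 genes, and the report gives a selection of them.

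The background ceiling, chosen after seeing the data, was 2.07, the highest log2 value of 50 negative-control probe sets over the 6 arrays. A gene with a whole group at or under it has only a bound, written "at least", from the other group's mean against the ceiling. Genes at background in both groups numbered 180. Of the 184 control probe sets, 14 were called higher and 40 lower by limma in a test of all probe sets: 0 of the 50 negative controls, but 16 of 17 for ribosomal RNA and 10 of 26 bacterial and phage hybridisation controls above background were lower (median log2 fold change of the last -0.25).

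Control and myriocin samples share replicate numbers in the labels. Deviations from the group means correlated at 0.167, 0.238 and 0.171 for equal numbers and between -0.159 and -0.0496 for unequal ones, across genes. Deviations cancel within each group, so the negative values follow from the positive ones and are no separate evidence. Whether the numbers pair the samples is not settled, and the fit with the pairs as a block is an alternative.

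The scripts were tested on simulated arrays with the real means and spreads of the 5519 genes. Of genes changed by 0.5, 1 and 2 log2 units, 27 of 50, 80 of 100 and 44 of 50 were recovered, each in the right direction, and 7 of 5289 unchanged genes were called, 4.43% of the calls. Missed genes at 2 log2 units had replicate SDs of 0.333 or more. Camera called the 1 changed list and 0 of 30 unchanged ones, in simulated data whose genes vary independently, which those of real lists do not.

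Alternatives were quantile normalisation, equal array medians, the dimmest 25% of genes left out, the mean of a gene's probe sets, an intensity trend with robust variance, the block, each replicate left out, other thresholds, an equal-variance test, camera with estimated correlations and fry. Arrays scaled to the mean of the hybridisation controls, probe sets naming several genes, genes at background left out and values floored at background were added after seeing the data. Figures were drawn with matplotlib 3.10.9.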

Results

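Gene expression was measured in cultures of the wild-type budding yeast strain DBY746 grown with or without myriocin, a natural product that inhibits serine palmitoyltransferase, the first enzyme of sphingolipid synthesis. The 6 samples comprised 3 biological replicates of control cells, which received the ethanol vehicle, and 3 of cells grown with 300 ng/ml myriocin. Cells of both groups were collected at an A600 of 2. Each sample was hybridised to 1 single-colour array, and 5519 genes were read by a probe set naming that gene alone. Between 95.4% and 95.8% of these genes lay above the background ceiling on each array, and median log2 values lay between 11.01 and 11.03. The number of arrays limits the precision: the median standard error (SE) of a log2 fold change was 0.11.

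The first question was which genes changed in cells grown with myriocin. The 12 largest increases included JEN1, the lactate and pyruvate transporter, CYB2, the lactate dehydrogenase of mitochondria, and TKL2, a transketolase. JEN1 rose by 9.28 on the log2 scale (SE 0.51, n = 3 per group, limma adjusted p = 0.000132) and CYB2 by 7.78. These folds are read against values near background: the control values of JEN1, 2.09 to 2.11, lay just above the ceiling of 2.07, and 1 of 3 control arrays of CYB2, SPG1 and YER053C-A lay at or under it. TKL2 was at background in all control arrays and was at least 484-fold higher with myriocin. SPG1, YER053C-A, FMP45, NCA3, RTN2, RGI2, AGX1, the cell-surface flocculin gene FLO11 and the catalase gene CTT1 completed the 12 highest, with log2 fold changes from 8.75 for SPG1 to 6.46 for CTT1. The deepest decreases were in VEL1 and YOR387C, which went from mean log2 values of 13.31 in control cells to background in every myriocin array. VEL1 was at least 2419-fold lower and YOR387C at least 2422-fold lower. The log2 fold changes were -7.15 (SE 0.67) for the transporter gene AQR1, -5.77 for the pheromone-regulated gene PRM2, -5.15 for the cell wall mannoprotein gene TIR3 and -4.48 for the ADP/ATP carrier gene AAC3. DOC1, a subunit of the anaphase-promoting complex, was at least 58.1-fold lower. YOL014W, YAL064W, YMR230W-A, YDL241W and the GPI-anchor synthesis gene GPI19 completed the 12 lowest, with log2 fold changes from -4.93 for YOL014W to -4.22 for GPI19.

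**Figure D1:**
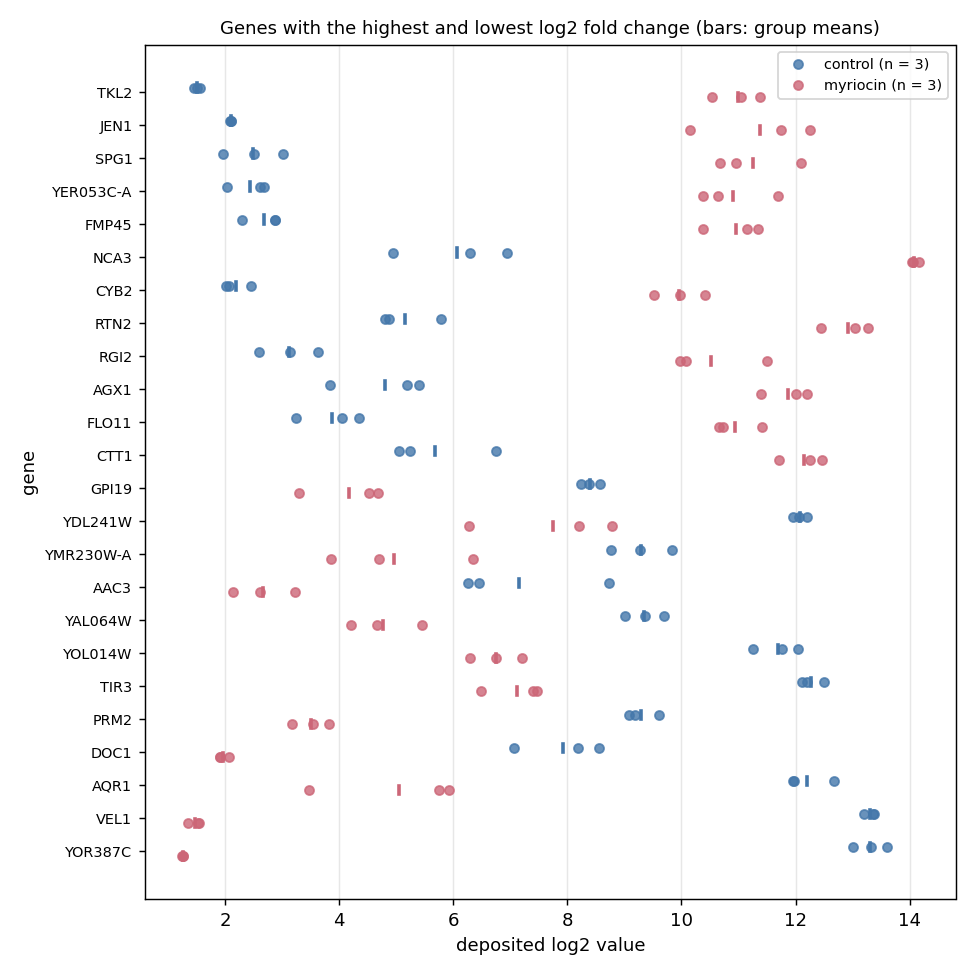
Deposited log2 values (x axis) of the 12 genes with the highest and the 12 with the lowest log2 fold change, 1 point per array and a bar at each mean of 3 arrays. For each gene the 3 myriocin values lie on one side of the 3 control values, and VEL1 and YOR387C lie at 13.31 on average in control cells.

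In all, 3048 genes, or 55.2%, passed limma's test, 1450 higher and 1598 lower with myriocin. Of these, 511 were at least 2-fold higher, 415 were at least 2-fold lower, and 1222 changed by less than 1.5-fold. The groups did not overlap for 3698 genes (67%, where chance gives 10%), and the first principal component, which separated the groups, held 88.9% of the variance. Probe sets for ribosomal RNA, which are controls on this array, differed with the treatment too: 16 of 17 were lower with myriocin, with a median log2 fold change of -1.61. The hybridisation controls added to each array were lower too, all 26 probe sets above background by 0.04 to 0.96 on the log2 scale and 10 of them past limma's test. With the arrays scaled to these controls, the median log2 fold change of all genes moved from -0.03 to 0.29, each gene's by the same 0.315, and 2229 genes were called higher and 670 lower. The brightest controls, those of phage cre with means of 14.34 to 15.27 in control arrays, fell by only 0.04 to 0.18. For genes of like signal that scaling adds more than these controls fell. Decreases and increases below therefore describe genes relative to the rest, and small ones depend on this scale.

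The next question was how genes of the pathway that myriocin blocks responded. Genes of sphingolipid synthesis were lower in the deposited values: 11 of 22 fell and none rose, over all genes tested, and 11 fell when adjusted over the list alone, while 6 fell and 3 rose with the arrays scaled to the hybridisation controls. ORM1, which encodes a regulator of serine palmitoyltransferase, fell by 1.39 (SE 0.10, limma adjusted p = 0.000251). ORM2, its paralog, had a log2 fold change of -0.01 (limma adjusted p = 0.892). The genes of very-long-chain fatty acid elongation ELO2, PHS1, ELO3 and IFA38 fell by 1.11, 0.79, 0.76 and 0.29, the last turning to 0.025 with that scaling. The ceramide synthase genes LAC1 and LAG1 fell by 0.66 and 0.62, the inositol phosphorylceramide synthase subunit gene KEI1 and the mannosyl-inositol-phosphotransferase gene IPT1 by 0.74 each, and the reductase gene TSC10 by 0.47. Of the genes of the target enzyme, TSC3 fell by 0.26 (SE 0.07), turning to 0.055 with that scaling, while LCB1 and LCB2 had log2 fold changes of -0.39 (SE 0.16, limma adjusted p = 0.0841) and -0.17 (SE 0.12, limma adjusted p = 0.241). The list as a whole was shifted lower against other genes (camera adjusted p = 0.00216), with adjusted p = 0.623 with an estimated correlation. With the arrays scaled to the hybridisation controls, the calls of LAC1, LAG1 and TSC10 were lost (limma adjusted p = 0.0552, 0.0752 and 0.425). The calls of TSC3 and IFA38 were lost also without single arrays (limma adjusted p between 0.0536 and 0.0566 without control replicate 2 or 3 for TSC3, and between 0.0562 and 0.0745 without control replicate 1 or 2 or myriocin replicate 1 for IFA38).

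**Figure D2:**
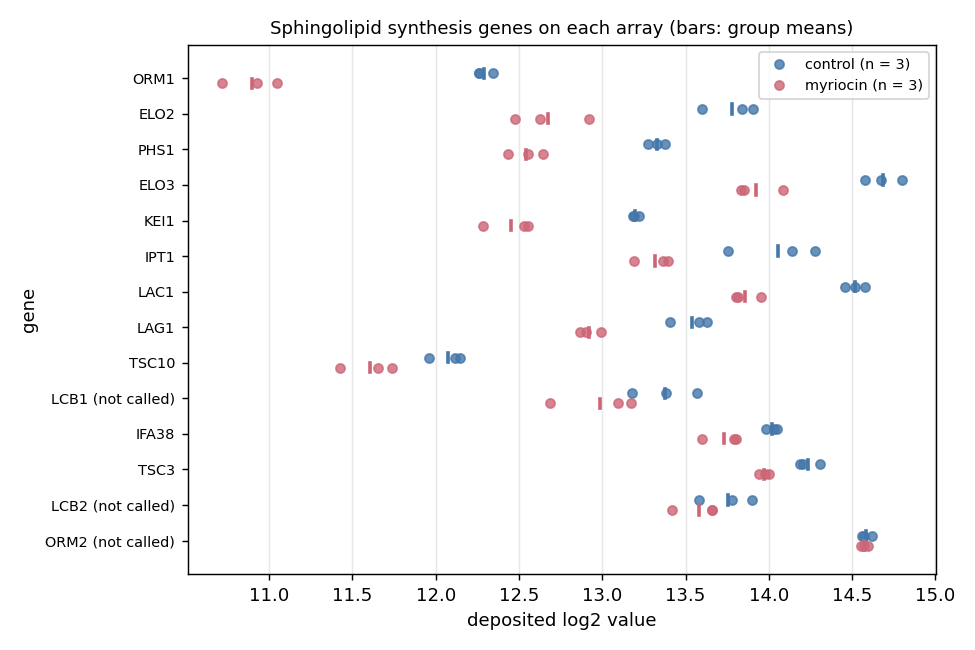
Deposited log2 values (x axis) of the sphingolipid synthesis genes that passed the test and of LCB1, LCB2 and ORM2, 1 point per array and a bar at each mean of 3 arrays. ORM1 shows the largest decrease, 1.39 on the log2 scale, and ORM2 overlaps between the groups.

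Genes of long-chain base and ceramide turnover moved both ways: 5 of 9 rose and 2 fell, over all genes tested and when adjusted over the list alone. The kinase gene LCB5 rose by 1.02 (SE 0.19) and the phosphatase gene LCB3 fell by 0.90 (SE 0.19), and the list was not shifted (camera adjusted p = 0.122).

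The lists fixed for other processes showed which gene groups moved together. Over all 37 lists, with sphingolipid synthesis among the lower ones, 11 were shifted higher and 8 lower by camera. Every one of these 19 calls was lost with an estimated correlation, whose adjusted p is given beside each list. Counts of members called by limma are given beside each list, to be read against 1450 higher and 1598 lower among all 5519 genes.

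Genes for using carbon sources other than glucose rose. In gluconeogenesis and the glyoxylate cycle 14 of 16 rose (median log2 fold change 3.11, camera adjusted p = 1.46e-05; adjusted p = 0.56 with an estimated correlation). They included ADH2, which rose by 6.07, FBP1, at least 29.3-fold higher, and the acetate transporter gene ADY2, at least 22.8-fold higher. FBP1 was at least 16.2-fold higher without myriocin replicate 1 and 61.9-fold without myriocin replicate 2. ADY2 was at least 11.1-fold higher without myriocin replicate 1 and 34.5-fold without myriocin replicate 3. In peroxisomal beta-oxidation 14 of 16 rose (median 1.55, camera adjusted p = 2.45e-05; adjusted p = 0.56 with an estimated correlation), led by CRC1 and SPS19 at 4.40 and 3.84, and POT1 was at least 6.24-fold higher, or 3.40-fold without myriocin replicate 1 and 11.5-fold without myriocin replicate 2. The call of POT1 was lost with values floored at background (limma adjusted p = 0.0598) and without any 1 control array or myriocin replicate 3 (0.052 to 0.0667). Of the nuclear-encoded respiratory chain and ATP synthase 33 of 34 rose (median 0.79, camera adjusted p = 1.55e-11; adjusted p = 0.56 with an estimated correlation), with NDI1 at 2.45 and QCR2 at 1.46. In the TCA cycle 14 of 17 rose (median 0.76, camera adjusted p = 1.46e-05; adjusted p = 0.61 with an estimated correlation), with CIT3 at 2.25 and SDH2 at 1.31. The trehalose and glycogen genes, which serve carbohydrate storage, rose in 12 of 15 cases (median 1.23, camera adjusted p = 1.46e-05; adjusted p = 0.56 with an estimated correlation), with NTH2 at 3.14 and GDB1 at 2.47. These counts are over all genes tested, and when adjusted over the list alone they were the same, but for 1 gene of gluconeogenesis and the glyoxylate cycle called lower.

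Stress and nitrogen-starvation genes rose as well. Of the general stress genes bound by Msn2 and Msn4, 31 of 36 rose and PDE2 fell (median 1.23, camera adjusted p = 9.25e-11; adjusted p = 0.56 with an estimated correlation), with ALD3 at 5.83 and SIP18 at 4.18. Of genes under nitrogen catabolite repression 18 of 26 rose and DAL1 fell (median 1.10, camera adjusted p = 2.77e-05; adjusted p = 0.56 with an estimated correlation), with PUT1 and CAR2 at 3.41 and 3.06. In autophagy 16 of 32 rose and 3 fell, or 23 rose and 0 fell with the arrays scaled to the hybridisation controls (median 0.49, or 0.80 with that scaling, camera adjusted p = 0.00234; adjusted p = 0.56 with an estimated correlation). ATG34, ATG2 and the mitophagy receptor gene ATG32 rose by 3.24, 2.81 and 2.47. Smaller shifts were seen in G1/S genes (camera adjusted p = 0.011, or 0.795 with an estimated correlation). Over all genes tested 9 of 34 rose and 2 fell, and the share that rose was close to that of all genes. When adjusted over the list alone 7 rose and 0 fell, and 19 rose and 0 fell with that scaling. The cyclin gene CLN2 rose by 1.63. Among cell wall integrity genes 12 of 28 rose and 2 fell, or 18 rose and 0 fell with that scaling (camera adjusted p = 0.022; adjusted p = 0.749 with an estimated correlation). PIR3 rose by 3.09 and the glucan synthase gene GSC2 by 1.54. Of the oxidative stress genes under Yap1 10 of 24 rose and 2 fell (camera adjusted p = 0.0487; adjusted p = 0.56 with an estimated correlation), with GTT2 at 3.51, and with the samples paired by replicate number this call was lost (camera adjusted p = 0.0624). Leaving out 1 array also ended calls: that of G1/S genes without control replicate 1 (camera adjusted p = 0.0545), of cell wall genes without control replicate 3 (0.0588) or myriocin replicate 3 (0.0544), and of oxidative stress genes without control replicate 1 or 3 or myriocin replicate 3 (0.0588 to 0.102). The oxidative stress call was lost as well with the dimmest genes left out (camera adjusted p = 0.376), with values floored at background (0.0818) and with background genes left out (0.0533). Adjusted over the list alone, 32 general stress genes rose, 19 nitrogen genes rose and 2 fell, 17 autophagy genes rose, and the other counts of this paragraph apart from G1/S genes were the same. With the arrays scaled to the hybridisation controls the calls of ATG27, ATG5, PRM5, RLM1, RAD27, PCL2 and DAL1 were lost (limma adjusted p = 0.124, 0.135, 0.45, 0.263, 0.382, 0.179 and 0.73). DAL1 lost its call also without any 1 array but control replicate 3 (limma adjusted p from 0.0716 to 0.131), PCL2 without any 1 array but myriocin replicate 2 (0.0577 to 0.113). RAD27 lost its call without control replicate 2 or 3 or myriocin replicate 2 or 3 (0.0641 to 0.119), and PRM5 without control replicate 1 or 2 or myriocin replicate 1 or 3 (0.074 to 0.0893).

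The mitochondrial ribosome moved against the respiratory chain. Of the 70 genes on the list for its proteins 41 fell and RSM7 and MRP8 rose (median -0.40, camera adjusted p = 3.25e-07, or 0.56 with an estimated correlation). MRPL3 and RSM25 fell by 1.60 and 1.54. Whether MRP8 encodes a protein of that ribosome was not checked. MRP8 rose by 0.21 and lost its call with the samples paired by replicate number (limma adjusted p = 0.0549) and without any 1 array (0.0524 to 0.133). Of cytosolic ribosomal protein genes 48 of 120 fell over all genes tested, and 3 when adjusted over the list alone (median -0.18, or 0.13 with the arrays scaled to the hybridisation controls, camera adjusted p = 4.31e-07; adjusted p = 0.749 with an estimated correlation). Of proteasome genes 20 of 32 fell, by small amounts, or 0 fell and 1 rose with that scaling (median -0.22, or 0.09 with that scaling, camera adjusted p = 0.000474; adjusted p = 0.71 with an estimated correlation). RPT3 fell by 0.50, or had a log2 fold change of -0.18 with that scaling (limma adjusted p = 0.274). Adjusted over the list alone, 20 proteasome genes fell, and 41 mitochondrial ribosomal protein genes fell and 2 rose. With that scaling neither the cytosolic ribosomal protein nor the proteasome list was shifted (camera adjusted p = 0.199 and 0.375), 2 cytosolic ribosomal protein genes fell and 2 rose, and 12 mitochondrial ribosomal protein genes fell and 4 rose, with a median of -0.08.

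Zinc-regulated genes fell in 9 of 12 cases (median -0.90, or -0.59 with the arrays scaled to the hybridisation controls, camera adjusted p = 0.00073; adjusted p = 0.56 with an estimated correlation). ZPS1 fell by 3.62 (SE 0.13), the alcohol dehydrogenase gene ADH4 by 2.86 (SE 0.07) and ZAP1, the regulator of the group, by 1.39 (SE 0.09), while the zinc transporter gene ZRT2 rose by 0.44. Genes of the unfolded protein response and ER-associated degradation fell in 14 of 23 cases, or 11 with that scaling (median -0.52, or -0.20 with that scaling, camera adjusted p = 0.00171; adjusted p = 0.623 with an estimated correlation), HRD3 by 1.39 and EUG1 by 1.13, while HAC1, the transcription factor of that response, rose by 0.92 and ULI1 by 2.38. Mating pheromone genes fell in 14 of 25 cases, or 10 with that scaling (median -0.57, or -0.25 with that scaling, camera adjusted p = 0.000356; adjusted p = 0.616 with an estimated correlation), PRM1 by 3.94 and FIG2 by 3.02, while FUS3 rose by 0.59. In inositol, phospholipid and fatty acid synthesis 7 of 20 fell, or 4 fell and 4 rose with that scaling (median -0.13, camera adjusted p = 0.0382; adjusted p = 0.743 with an estimated correlation). EPT1 fell by 1.49. The call of this list was lost without control replicate 1 or 2 or myriocin replicate 1 (camera adjusted p from 0.0545 to 0.0729), under quantile normalisation (0.0702), with the dimmest genes left out (0.0528) and with that scaling (0.31), where its median turned to 0.19. Adjusted over the list alone, 15 genes of the unfolded protein response list fell, and the other counts of this paragraph were the same.

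**Figure D3:**
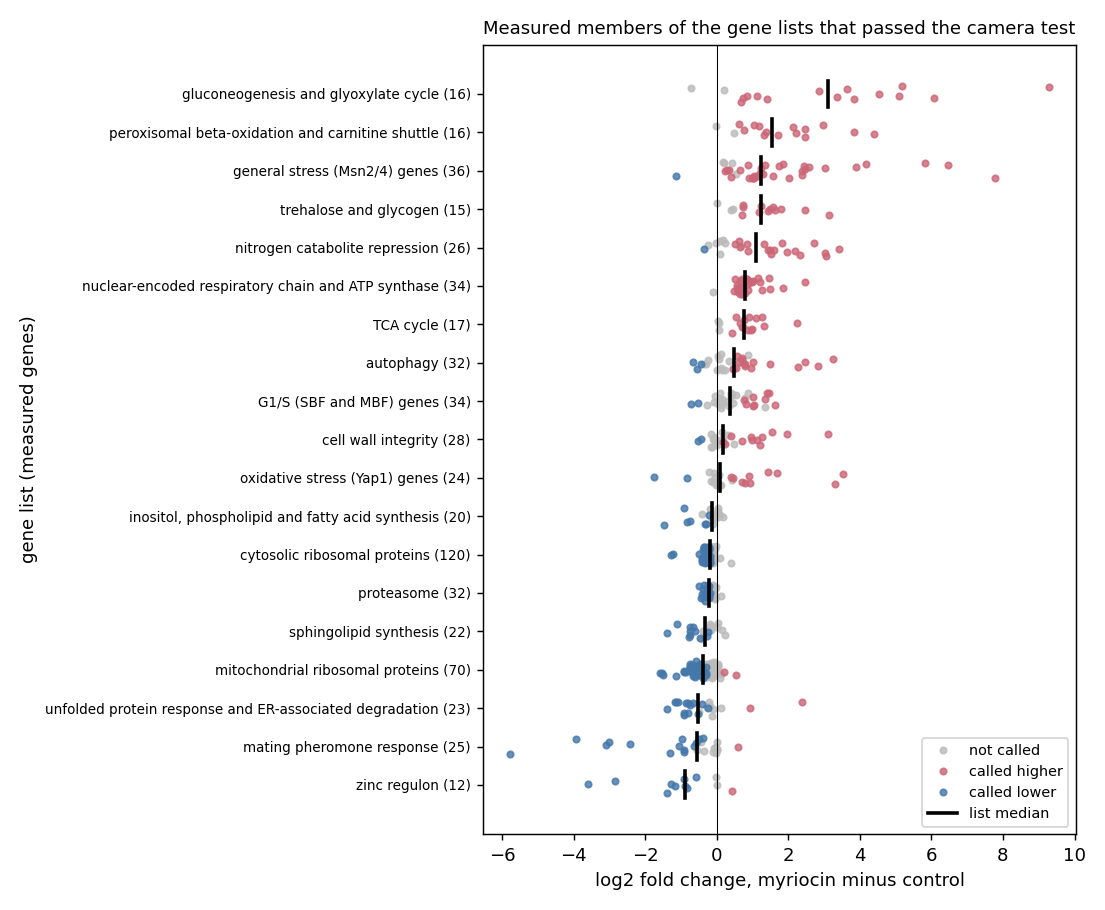
Log2 fold change, myriocin minus control (x axis), of every measured gene of the 19 lists that passed camera with its preset correlation, coloured by limma's call, with a bar at each list's median. Medians run from -0.90 in the zinc regulon to 3.11 in gluconeogenesis and the glyoxylate cycle. Those of inositol and phospholipid, cytosolic ribosomal protein and proteasome genes turn positive with the arrays scaled to the hybridisation controls. That scaling adds 0.315 to every gene, more than the brightest of these controls fell.

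Other fixed lists were not shifted by camera in the main fit, though single members changed. The glucose transporter gene HXT1 fell by 2.59 and HXT5 rose by 6.13. The siderophore transporter genes SIT1 and ENB1 fell by 2.45 and 1.95, and the phosphate transporter gene PHO84 was at least 10.5-fold higher, or 5.95-fold without myriocin replicate 3 and 16.9-fold without myriocin replicate 1. Among ergosterol synthesis genes 4 of 24 rose and 8 fell over all genes tested and when adjusted over the list alone, HMG1 by 0.89, and with the arrays scaled to the hybridisation controls 10 rose and 2 fell. Of ribosome biogenesis genes 11 of 69 fell and 1 rose, 7 fell and 0 rose when adjusted over the list alone, and 17 rose and 3 fell with that scaling. UTP15 fell by 1.28 in the deposited values. Of glycolysis and ethanol formation genes 1 of 16 rose and 1 fell, 1 fell and 0 rose when adjusted over the list alone, and 5 rose and 0 fell with that scaling. The chaperone gene SSA4 rose by 2.52 and PAU5 by 2.63.

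The authors' deposited table of changed probe sets lists 1507 higher and 1734 lower, chosen on these same arrays and so no independent evidence. Of the genes tested here, 2916 were called and also stood in that table, 132 were called without being in it, 250 were in it without being called, and 0 went the opposite way. The authors' p-values in that table are unadjusted and reach 0.0478, whereas the calls here use adjusted p. At an unadjusted limma p under 0.05, 3038 genes were shared.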

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

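The tests on values near background and on glucose transporters were chosen only after the result was seen. Among probe sets outside the main measurement, 20 of the 82 naming several genes were higher in myriocin arrays than in control arrays, with a highest log2 fold change of 5.83, and 19 were lower. Of the 89 unnamed probe sets, 2 were higher and 3 lower.

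With 3 arrays against 3, the 10 splits are too few for a share under 0.05. The real split gave 3048 genes and the highest other split 0 by limma, with 3 to 108 genes at an unadjusted p under 0.05 in the other splits. Each other split mixes control and myriocin arrays within its groups, which widens the spread that limma tests against. Few calls there were thus set by construction, and the contrast with 3048 gives no support. For gene lists the real split gave 19 and the highest other split also 19, so 2 of the 10 splits reached that count. That other split, like the real one, parts all 3 same-numbered pairs; the remaining splits that do so gave 14 lists each, and those that part 1 pair gave 9 to 17. Every other split holds part of the treatment difference by construction, since its groups are unequally mixed: its fold changes correlated with the real ones at sizes between 0.828 and 0.942 across genes, and 7 to 15 of its lists were among the real 19.

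VEL1 and YOR387C lay at background in all myriocin arrays. Loss of a chromosome end is argued against by genes nearer the end that stayed above background on all myriocin arrays with a log2 fold change above -1. These were 2 of 3 measured genes between YOR387C and the right end of chromosome XV, YOR389W and YOR394C-A. The third, FEX1, also stayed above background but fell by 1.03 (limma adjusted p = 0.00108). Between VEL1 and the left end of chromosome VII, 1 of 4 measured genes met the bound, YGL258W-A, with group means of 3.92 and 5.87. Whether these probe sets read close copies elsewhere, which could hide a loss, was not tested. The other measured genes between VEL1 and that end had means of 1.51 to 2.07 in control cells, at or under the ceiling. They could not show a loss. VEL1 and YOR387C may follow lower activity of the zinc regulator Zap1. The median of 12 further Zap1-linked genes, -0.36, lay at percentile 3.47 of 10000 random lists matched on expression. That percentile lies close to the bound of 5 set for it: leaving out 1 gene gave percentiles from 1.31 to 8.84, and 6 of the 12 removals took it to 5 or more. Each of those 6 gave the same median, -0.29. Removing any gene from the lower side of the list leaves the same middle gene. The equal medians therefore do not show whether a particular member carries the result, and the hypothesis stays weakly backed. Whether both probe sets read the same RNA was not tested, as probe sequences were not used here.

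Respiratory chain genes were higher while mitochondrial ribosomal protein genes were lower, the latter with a median of -0.08 with the arrays scaled to the hybridisation controls. A bias that follows signal level is argued against: 0% of 10000 random lists matched on signal had medians as far from 0, for either list. A rise shared by mitochondrial genes in general is argued against as well. Genes of mitochondrial protein import had a median of -0.33, or -0.013 with that scaling, and it differs from that of the respiratory chain by -1.12. Whether mitochondrial content changed cannot be told from these RNA values, as content was not measured. A candidate explanation that stays open is higher HAP4, the activator subunit for respiratory genes, which rose by 0.55 (limma adjusted p = 0.00869), or 0.87 with that scaling, and its activity was not measured.

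Glucose-repressed and general stress genes were higher. Flooring values at background kept 94.9% or more of the medians of both lists. That test could hardly move them, since only 4 of 16 genes of gluconeogenesis and the glyoxylate cycle and 1 of 36 general stress genes had 1 group at background. Values at background thus concern few members. Dim values just above the ceiling were addressed by leaving out the dimmest genes, where both lists kept their camera call. That argues against dim members as the only source of these calls, while the medians in that setting are not reported here. Less glucose left at harvest in the myriocin cultures remains possible: HXT1, used at high glucose, fell by 2.59. HXT3 fell by 0.26 (limma adjusted p = 0.0242) but turned to 0.054 (limma adjusted p = 0.732) with the arrays scaled to the hybridisation controls. That scaling adds 0.315. Phage cre controls with signals near that of HXT3 (14.73), at 14.66 to 14.82 in control arrays, fell by 0.09 to 0.13. Any support from HXT3 therefore depends on the scaling. Less glucose cannot be told apart from a direct response here. A probe set shared by the low-glucose transporter genes HXT6 and HXT7 had a log2 fold change of 0.13 (limma adjusted p = 0.215) in the deposited values. Whether so bright a probe set, at 14.74 in control arrays, could show a rise was not tested. HXT2 and HXT4 were not called either (limma adjusted p = 0.0785 and 0.0959), while HXT5 rose by 6.13. That scaling would raise the shared probe set too, and glucose was not measured in these files.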

How the results depend on the processing

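Scaling to hybridisation controls, flooring at background, leaving out background genes and testing probe sets that name several genes were chosen after seeing the data. Of 154 called genes among the 157 that the naming rule takes, 127 kept the call in each limma setting that tested them. Of the 19 shifted lists, 13 kept the call in each setting of camera with its preset correlation. The exceptions were inositol and phospholipid synthesis, cell wall integrity, oxidative stress, G1/S, cytosolic ribosomal protein and proteasome genes. Some settings added a call. The seripauperin list (camera adjusted p = 0.0518 in the main fit) passed with the mean of a gene's probe sets, the intensity trend and the hybridisation-control scaling. It passed also without control replicate 1 or myriocin replicate 2. Hsf1-type chaperones passed without myriocin replicate 1. Scaling the arrays to the hybridisation controls moved the median of all genes to 0.29 and gave 2229 genes higher and 670 lower (76.9% higher), 6 sphingolipid synthesis genes lower and 3 higher, and 5 lists lower; TSC3 and IFA38 changed direction, to 0.055 and 0.025. That shift follows from the lower controls, and the cause of their difference was not tested. The brightest of them fell by less than the 0.315 added to every gene. The fit with replicate numbers as a block called 2943 genes; besides oxidative stress, RAD27 (limma adjusted p = 0.0772) and MRP8 (0.0549), it changed no other call among these genes and lists. Without 1 replicate, 2370 (without control replicate 2) to 2750 genes were called. Requiring a 2-fold change left 926 genes, 511 higher and 415 lower, and an adjusted p under 0.01 left 2007, of which 991 were lower, both by construction. Camera with estimated correlations called 0 lists, 0 higher and 0 lower, where fry called 22, 12 higher and 10 lower, and fry's mixed test, which asks for change in either direction, called 37. Fry asks whether a list's own members change, not whether they change more than other genes, so its calls do not back camera's. With 55.2% of all genes called, the mixed test could hardly fail, and it called the sporulation comparison list too. Turnover genes called higher numbered 2 with the dimmest genes left out, where fewer were tested, and those called lower 1 to 2 without 1 replicate; the cause was not tested. POT1, RAD27, PCL2 and DAL1 lost their calls with values floored at background (limma adjusted p = 0.0598, 0.0595, 0.0697 and 0.0566). Signal over background limits the 180 genes at background in both groups, for which no change could be read.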

Other observations

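The test of anaerobic genes was chosen only after some of its members were seen; the lists below were all written after the main results. Genes that modify and anchor proteins in the endoplasmic reticulum were lower with myriocin, in the deposited values and relative to other genes. Of 22 genes of GPI anchor synthesis other than GPI19, 17 fell and 1 rose (median log2 fold change -0.83, camera adjusted p = 0.000109 over 8 lists; adjusted p = 0.324 with an estimated correlation). Of 26 genes of N-glycosylation 18 fell and 0 rose (median -0.60, camera adjusted p = 0.000151; adjusted p = 0.373 with an estimated correlation). Of 26 genes of mitochondrial protein import 18 fell and 0 rose (median -0.33, camera adjusted p = 0.000206; adjusted p = 0.324 with an estimated correlation). With the arrays scaled to the hybridisation controls, 12 genes of GPI anchor synthesis fell and 1 rose, 10 of N-glycosylation fell and 2 rose, and 5 of mitochondrial protein import fell and 3 rose, with medians of -0.51, -0.29 and -0.013.

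The other 5 lists were not shifted by camera: peroxins (adjusted p = 0.0621), RNA polymerases I and III (0.123), anaerobic and hypoxic genes other than AAC3 and TIR3 (0.402), COPI and COPII coats (0.44) and thiamine synthesis other than THI21 (0.914). An extra or missing chromosome copy was tested across 16 chromosomes, and the largest distance of a chromosome's median log2 fold change from that of all genes was 0.0768.

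Ribosomal RNA probe sets had log2 fold changes from -3.85 to 0.04, and 16 of 17 were called lower by limma. Hybridisation controls had a median log2 fold change of -0.25, from -0.96 to -0.04. The difference between 3' and 5' control probe sets of the same transcript, myriocin minus control, was -0.27 for SPT15, -0.24 for EAF5, -0.14 for RIP1, -0.10 for ACT1, 0.02 for TDH1 and 0.08 for WBP1. Those of SPT15 (SDs within a group of 3 arrays 0.08 and 0.14), EAF5 (0.04 and 0.09) and ACT1 (0.05 and 0.04) exceeded the SD of either group, and those of RIP1 and WBP1 did not. That of TDH1, 0.023, exceeded the control SD (0.0215) but not the myriocin SD (0.0252). Whether a difference in RNA quality contributes to the gene changes was not tested.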
